A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

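RNA was measured in 6 samples of fission yeast grown in log phase in YES medium at 30 ºC, 3 of a wild-type strain and 3 of a strain with a duf89 deletion. Per the labels' protocols, RNA was purified with hot acid phenol, polyadenylated RNA was made into stranded Illumina TruSeq libraries, and these were sequenced with paired ends on an Illumina instrument. The protocol text names alternative models, and which library ran on which is not given in the sources used here. The series text says that the wild-type samples were deposited earlier with another series and were sequenced at the same time as the mutant. The labels of the deletion call its replicates biological; those of the wild type only number them, so its spread may be technical.

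The deposited counts are whole numbers of reads per gene. The submitters' processing notes name HISAT2 2.1.0, SAMtools, HTSeq 0.10.0, DESeq2 and DESeq and the build ASM294v2, without the role or order of each. The strand setting, the treatment of reads with several matches and any filter are not given in the sources used here. A second table holds the authors' own comparison: a log2 fold change, its standard error on the log2 scale, a test score (the Wald statistic), p-values, and average signal (mean normalized counts) per group, per the file headers. The mean of the group averages divided by the table's overall mean ran from 0.289 to 1.45, so the overall mean is not the mean of these groups alone. The authors' comparison was used only beside the refit.

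The count table has 6987 lines for 6986 genes, because one identifier occurs on 2 lines, which were summed. No line lacked a gene. Library totals ranged from 18244492 to 21572536 counts. Replicates were not duplicates: the chi-square per degree of freedom between libraries of one group ran from 5.85 to 15.6. Identifiers were matched to the RefSeq annotation of assembly ASM294v3, with 6833 genes (97.8%) matched. As this is not the build in the notes, it was used for names, neighbours, transcript length, GC content and repeated sequence (the share of 50-mers found elsewhere in the genome), and no coordinates are printed. The identifier SPAC806.04c, fixed for duf89 before the data were examined as a fallback to the symbol, belongs to the paralog duf8901 and was a wrong identifier. The gene named duf89 in RefSeq, SPCC1393.13, was used, and the paralog is reported beside it.

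Differential expression was computed with edgeR 4.0.16 in R 4.3.3 on the deposited counts (filterByExpr with a minimum count of 10, TMM factors, quasi-likelihood F test with group as the single term), adjusted by Benjamini-Hochberg over 6045 genes, with calls at an adjusted p below 0.05. The standard error was taken as the log2 fold change divided by the square root of F, and is approximate. CPM values, counts scaled to library size, use TMM-scaled totals, with a prior count of 2 on the log2 scale. On simulated data with the real means, totals and dispersions, in which 200 genes were changed, the test called 54% of genes changed 1.25-fold, 76% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 8 of 5826 unchanged genes (6025 genes tested). In the test of camera on simulated lists, 2 of 100 unshifted lists had a p under 0.05.

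Named genes follow a rule fixed before the data were examined. They are duf89, pho1, pho84 and tgp1 with 2 annotated neighbours on each side; the 10 largest rises and 10 largest falls among calls with a mean of at least 50 raw counts and separated libraries; and up to 4 called members of each fixed list by smallest adjusted p. A further set of falls outside mitochondrial and rRNA genes was added after the values were seen, and other list members were named after their values were seen. The 28 gene lists were also fixed before and were tested with camera in limma 3.58.1 (two-sided, preset correlation of 0.01, 27 lists with at least 3 tested members). Patterns of names for ribosomal proteins and ribosome biogenesis also caught antisense RNAs, so versions with protein genes were added.

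Alternatives planned before the data were examined were DESeq2 1.42.0, other scalings (DESeq2 size factors, upper quartile, total counts), no filter or a stricter one (at least 10 CPM in 3 libraries), protein-coding genes only, limma-voom, an adjusted p below 0.01, each library left out in turn, the replicate number as a block, and for lists an estimated correlation and fry. Added after the data were seen were fits without mitochondrial and rRNA genes, with offsets corrected for GC content, with cyclic loess (which removes a trend with abundance), and with genes under 10% repeated sequence. Figures were drawn with matplotlib. The p-values set the group difference against the spread between libraries of a group, and may not cover variation between wild-type cultures.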

Results

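Polyadenylated RNA of fission yeast (Schizosaccharomyces pombe) was sequenced from 3 libraries of a wild-type strain and 3 libraries of a strain in which duf89 had been replaced by a hygromycin resistance marker. All cultures were in log phase in rich YES medium. Duf89 is annotated as a metal-dependent phosphatase of metabolite repair. The libraries held between 18244492 and 21572536 counts over 6986 genes, and 6045 genes had enough counts to be tested. Libraries of one group correlated across genes with a Pearson r of 0.992 to 0.996 in wild type and 0.995 to 0.996 in the deletion. Between groups r lay between 0.968 and 0.984. Genes are not independent replicates, so these values only describe the libraries.

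The comparison asks how loss of Duf89 changes the transcriptome, and in particular the phosphate genes that are controlled by upstream long non-coding RNAs. The targeted gene was checked first. Expression of duf89 (SPCC1393.13, chromosome III) was 44.3 ± 2.1 CPM (counts scaled to library size) in wild type and 13.2 ± 3.9 CPM in the deletion (SD, n = 3 each), a log2 fold change of -1.74 (SE 0.16, adjusted p = 6.6e-05). The raw counts were 808, 897 and 794 in wild type and 229, 234 and 373 in the deletion. The gene was therefore lower in each deletion library than in each wild-type library, but counts remained. Which part of the locus the marker replaced is not given in the sources used here, so counts from retained untranslated sequence cannot be set apart. The paralog duf8901 (SPAC806.04c) measured 153.5 ± 3.8 CPM in wild type and 157.3 ± 5.9 CPM in the deletion and did not pass the test (log2 fold change 0.04, SE 0.05, adjusted p = 0.54).

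The 3 genes of the PHO regulon rose. Tgp1, a plasma membrane glycerophosphodiester transporter, rose 7.40-fold, from 23.5 ± 3.5 to 174.0 ± 5.9 CPM (log2 fold change 2.89, SE 0.09, adjusted p = 1.2e-07). Transcripts of pho1, which codes for the cell surface acid phosphatase, rose 3.35-fold, from 2452 ± 262 to 8224 ± 231 CPM (1.75, SE 0.07, adjusted p = 4.5e-07). Those of pho84, an inorganic phosphate transporter, rose from 1238 ± 119 to 3097 ± 220 CPM (1.32, SE 0.07, adjusted p = 2.3e-06). Each was higher in every deletion library than in every wild-type library. As a list they passed the camera test (adjusted p = 0.0027), which was lost with an estimated correlation (adjusted p = 0.34), in a list of 3 members. These genes are the stated subject of the study, so the list is no independent choice. The authors' deposited table gives log2 fold changes of 2.87, 1.73 and 1.30 for tgp1, pho1 and pho84, and -1.76 for duf89.

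**Figure D1:**
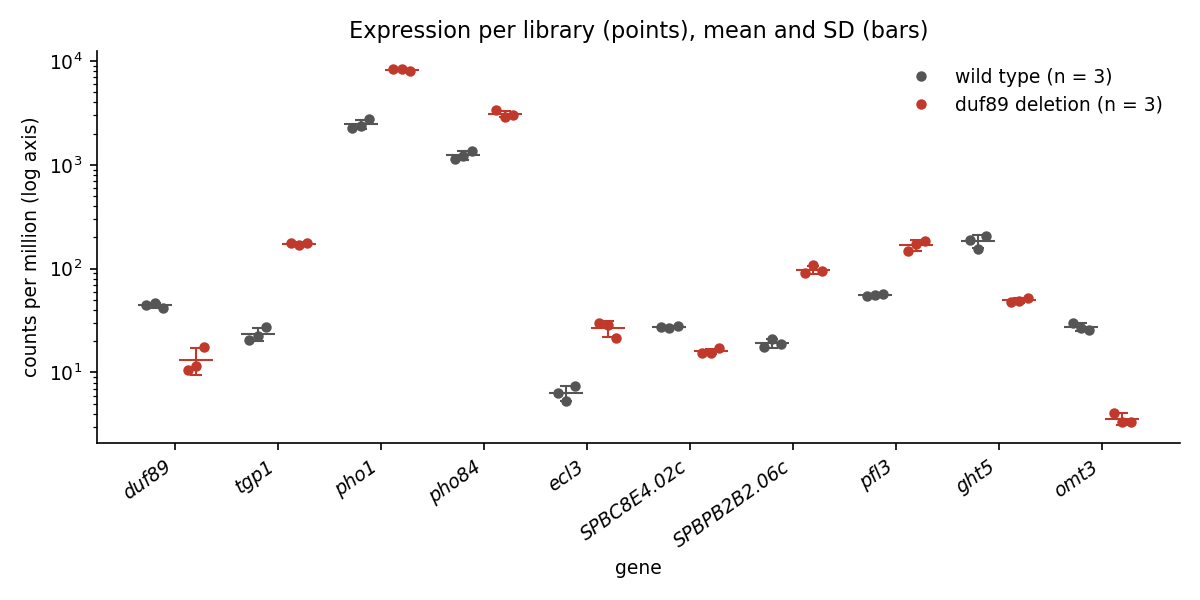
Expression (CPM) of 10 genes on a log axis, with 1 point per library, the group mean as a horizontal bar and the SD as an error bar (n = 3 per group, wild type grey, deletion red). The 3 deletion libraries lie above the 3 wild-type libraries for tgp1, pho1, pho84, ecl3, SPBPB2B2.06c and pfl3, and below them for duf89, SPBC8E4.02c, ght5 and omt3.

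Neighbours of these 4 genes were measured as well. On chromosome II, ecl3, annotated as an extender of chronological lifespan, lies on the far side of pho84 from pho1 and rose from 6.36 ± 1.08 to 26.8 ± 4.6 CPM (log2 fold change 2.08, SE 0.16, adjusted p = 2.1e-05). The next feature towards pho84 is SPBC8E4.02c, which the deposited annotation calls a species-specific protein and the RefSeq annotation lists as a synonym of the long non-coding RNA prt2. It fell from 27.6 ± 0.8 to 15.9 ± 1.0 CPM (-0.79, SE 0.09, adjusted p = 1.5e-04). In RefSeq prt2 overlaps pho84, so this value is uncertain. The prt RNA upstream of pho1 and the RNA nc-tgp1 were not analysed here. Next to tgp1, the non-coding RNA ncRNA.1343 fell (-0.67, SE 0.13, adjusted p = 0.0024), as did the predicted transporter gene SPBC1271.10c (-0.60, SE 0.06, adjusted p = 6.6e-05), which overlaps the end of tgp1 in RefSeq and is uncertain for that reason, while pet802 measured 0.07 (adjusted p = 0.42). The gene SPCC1393.12, directly upstream of duf89, rose (0.88, SE 0.08, adjusted p = 5.1e-05), and mrpl20 beyond it did not pass the test (0.08). On the other side, the phosphate transporter gene pho843, directly next to duf89, did not pass (0.10, adjusted p = 0.11), and lyr2 beyond it rose (0.76, adjusted p = 0.0027). Without deletion replicate 1 pho843 passed (0.17, adjusted p = 0.033), as it did with total counts only. Neighbours of pho1 on its other side, SPNCRNA.446 and fub2, had too few counts to be tested.

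Across the transcriptome, 1739 genes were higher and 1486 lower in the deletion at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), which is 53.3% of the genes tested. The wild-type libraries were deposited with another series, so a difference in preparation or processing between the groups cannot be told apart from genotype. Most changes were small. Of the 3225 calls 79.8% were under 1.5-fold, and 34 genes were higher and 150 lower by at least 2-fold (52 higher without wild-type replicate 3). In 3165 of the calls all 3 libraries of one group lay above all 3 of the other. Over all tested genes this held for 63.3%, where chance gives 10%. The balance of directions depended on the scaling: 53.9% of calls were higher as reported, 66.4% with total counts only, 47.7% with GC-corrected offsets (1593 higher, 1748 lower) and 47.6% with cyclic loess (1323 higher, 1458 lower). Among 4957 protein-coding genes 1646 were higher and 1184 lower (1549 and 1390 when fitted alone), and among 1015 annotated non-coding RNAs 85 were higher and 280 lower. The change ran with expression: across protein-coding genes Spearman's rho of the log2 fold change with the mean count was -0.41, and the eighth of genes with the highest counts had a median of -0.17.

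**Figure D2:**
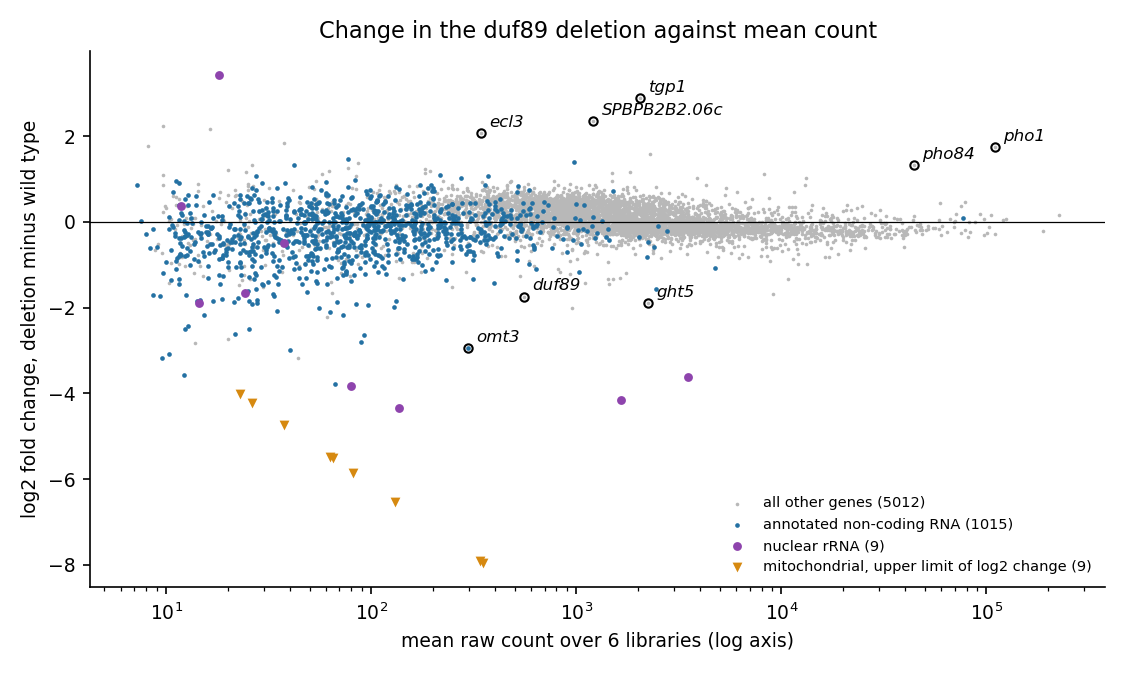
Log2 fold change (deletion minus wild type) of each tested gene against its mean raw count over 6 libraries on a log axis. Non-coding RNAs are blue, nuclear rRNA genes purple, other genes grey, and triangles mark the limit set by 3 counts per library for the 9 mitochondrial transcripts at 0 in the deletion. The PHO genes, ecl3 and SPBPB2B2.06c lie above 1 and ght5, duf89 and omt3 below -1.

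Besides tgp1, pho1, pho84 and ecl3, the 10 largest rises included SPBPB2B2.06c, a predicted extracellular 5′-nucleotidase, which rose 5.11-fold from 19.2 ± 1.9 to 98.1 ± 8.7 CPM (log2 fold change 2.35, SE 0.09, adjusted p = 4.3e-07). The flocculin gene pfl3 rose (1.58, SE 0.08), with 33.7% of its 50-mers repeated elsewhere in the genome. The remaining rises were SPNCRNA.1244 (1.47), pof9-antisense-1 (1.40), the meiotic septin gene spn5 (1.37) and num1 (1.26), also called mcp5, which anchors dynein at the cell cortex. The 10 largest falls were mostly mitochondrial and ribosomal RNA genes, with srp7, the 7SL RNA of the signal recognition particle (-3.79, SE 1.03, adjusted p = 0.012). The wild-type counts of srp7 were 36, 315 and 19, and without wild-type replicate 2 the value was -1.69. With limma-voom it did not pass (adjusted p = 0.058). A second set of 10 falls outside those classes was chosen after the values were seen. In it, the intergenic RNA omt3 fell from 27.5 ± 2.4 to 3.59 ± 0.45 CPM (-2.94, SE 0.13, adjusted p = 5.2e-07). The predicted urea transporter gene SPBC23G7.13c (-2.22), the predicted methyltransferase gene SPCC70.08c (-2.01) and ght5, the high-affinity glucose transporter gene (-1.89, SE 0.10, with 29.6% of its 50-mers repeated), fell as well. The other members were srp7 again and 5 antisense RNAs between -1.99 and -1.84, of which ubc4-antisense-1 and SPNCRNA.1491 measured -1.52 and -1.33 without wild-type replicate 1.

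Mitochondrial transcripts had no counts in the deletion libraries. All 38 mitochondrial features were at 0 in the 3 deletion libraries, whereas the wild-type libraries held 2064, 2920 and 1813 mitochondrial counts. The 7 tested members of the fixed list (cox1, cox2, cox3, cob1, atp6, atp9 and SPMIT.06) were at least 16.2-fold to 93.1-fold lower, with a median of at least 44.5-fold, taking 3 counts per library as the floor. The mitochondrial 15S and 21S rRNAs were at least 249-fold and 240-fold lower. These bounds cover counting error only. They would not describe RNA levels if mitochondrial features went uncounted in the deletion libraries, which is weighed below. The list passed camera (adjusted p = 4.1e-09, and adjusted p = 0.34 with an estimated correlation). Nuclear rRNA counts were 9973, 11464 and 9005 in wild type and 849, 862 and 1164 in the deletion. The copies SPRRNA.44, SPRRNA.46 and SPRRNA.48 fell (-4.33, -4.14 and -3.82) and SPRRNA.49 fell (-3.62), whereas SPRRNA.45 rose (3.43). Such copies share nearly all of their sequence, so the values of single copies are uncertain. In the list of rRNA, snoRNA, snRNA and tRNA genes 2 of 41 tested members were higher and 12 lower (median -0.06, also with the mitochondrial rRNAs at their bound; camera adjusted p = 0.062). The list passed when wild-type replicate 2 (0.042), wild-type replicate 3 (0.046) or deletion replicate 1 (0.037), 2 (0.031) or 3 (0.0049) was left out. That median was positive with total counts only, with cyclic loess and without the mitochondrial and rRNA genes.

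Of 138 tested entries in the list of cytosolic ribosomal proteins 90 fell and 3 rose (median -0.18, camera adjusted p = 1.9e-09, and adjusted p = 0.34 with an estimated correlation). The list included 7 antisense RNAs; among its 131 protein genes 89 fell and 3 rose. These counts depended on the scaling: 64 fell and 8 rose with total counts, 59 fell and 11 rose with GC-corrected offsets, and 23 fell and 16 rose with cyclic loess. Examples are rpl35a (-0.35, SE 0.04), rps27 (-0.33) and rps21 (-0.32). These are among the most abundant mRNAs, and after removal of the trend with abundance the list no longer passed (adjusted p = 0.80, median -0.01 over the protein genes). The curve that removes the trend is fitted in part to these same genes. Of 37 ribosome biogenesis entries 20 rose and 8 fell, among them nop2 (0.36, SE 0.05), utp5 (0.40) and nop14 (0.36). The camera test gave an adjusted p of 0.13, and 0.029 when its 4 antisense entries, of which utp5-antisense-1 fell by 1.32, were left out. With cyclic loess the whole list passed (0.047), and with an estimated correlation its adjusted p was 0.46. Of 10 histone genes 9 fell (median -0.23, adjusted p = 0.0027, and adjusted p = 0.37 with an estimated correlation), led by hta2 (-0.48, SE 0.04) and hta1 (-0.46). With total counts 5 of the histone genes were lower, and with cyclic loess 3 (median -0.09), where the list no longer passed (adjusted p = 0.19).

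In the core environmental stress response 9 of 14 members fell and 1 rose (median -0.43, adjusted p = 0.010, and adjusted p = 0.35 with an estimated correlation). The small heat shock protein gene hsp9 fell by 1.68 (SE 0.05), the trehalose synthesis gene tps1 by 0.81 and the catalase gene ctt1 by 0.81. Of 14 heat shock proteins and chaperones 8 fell, with the Hsp70 gene ssa1 (-1.33, SE 0.13) and hsp10 (-0.46) among them, and 1, wos2, rose (0.24); the list test gave an adjusted p of 0.062, but 0.042 without wild-type replicate 3, 0.037 without deletion replicate 1 and 0.046 without deletion replicate 2. With total counts 7 of them fell and 3 rose. Among iron uptake genes 5 of 10 fell, and 8 with cyclic loess (median -0.29, adjusted p = 0.011, and adjusted p = 0.34 with an estimated correlation). They included the ferric reductase gene frp1 (-1.40, SE 0.20), the siderophore transporter gene str1 (-1.25, SE 0.17), the iron permease gene fip1 (-1.02) and fep1 (-0.29), the repressor of iron uptake. Of 8 hexose transporter genes 5 fell, with ght5 at -1.89 and ght1 at -0.97, and ght2 rose (0.39; list adjusted p = 0.062). The list passed without wild-type replicate 2 (0.038) or 3 (0.046) and without deletion replicate 2 (0.046) or 3 (0.033). Of 8 glucose-repressed genes 4 fell, with adh4 (-0.84) and ght3 (-0.89), and mae2 rose (0.37; list adjusted p = 0.13). Among 14 glycolytic and fermentation genes 8 rose, such as eno101 (0.46) and tdh1 (0.43), and 2 fell (list adjusted p = 0.13). With GC-corrected offsets 11 rose and with cyclic loess 12, and the 2 falls were no longer called. That list passed without deletion replicate 2 (0.032), with GC-corrected offsets (0.0015) and after removal of the trend with abundance (6.2e-05); its adjusted p ran up to 0.69 with an estimated correlation. In the nitrogen list 6 of 11 members fell, including isp5 (-0.71) and mei2 (-0.93), and 2 rose, including isp4 (0.67; list adjusted p = 0.091, but 0.046 without deletion replicate 1 and 0.018 with cyclic loess). Thiamine-repressed genes had 2 of 5 members lower (4 with cyclic loess), thi9 (-0.42) and thi4 (-0.27; list adjusted p = 0.14). The call of thi4 was lost without deletion replicate 1 (-0.19, adjusted p = 0.097) and with total counts (-0.20, adjusted p = 0.059). With total counts 1 of the 5 members was lower.

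**Figure D3:**
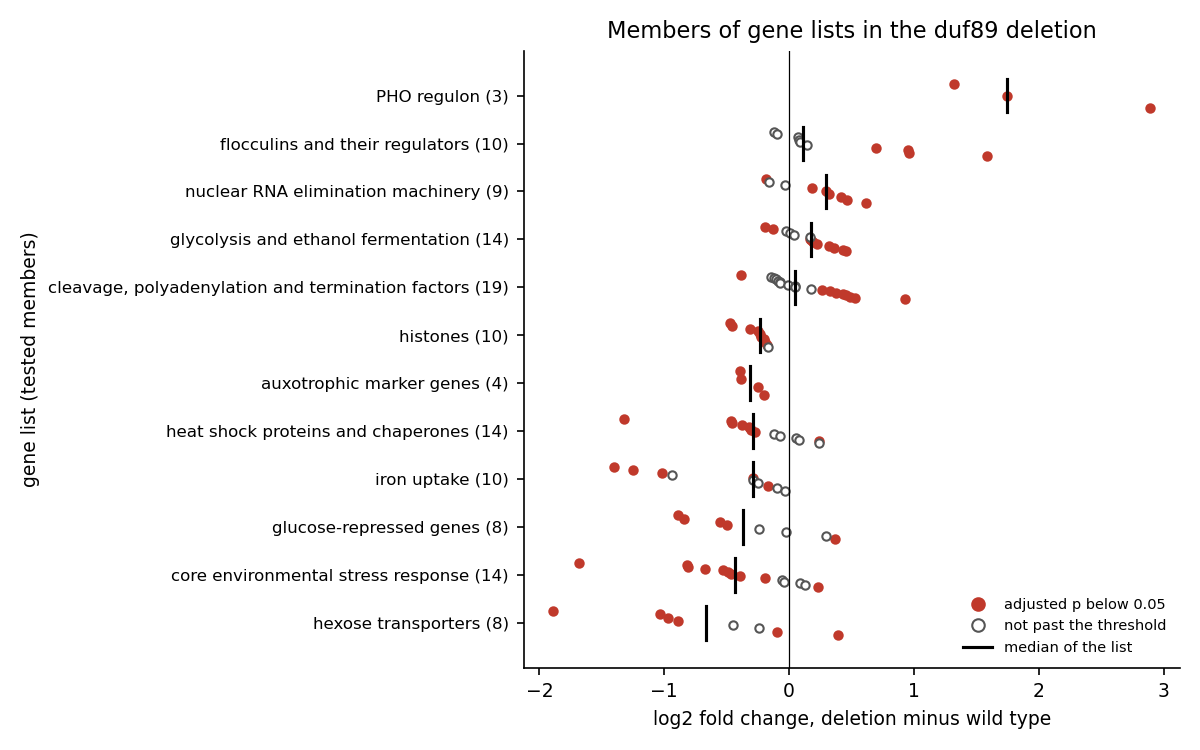
Log2 fold change (deletion minus wild type) of the tested members of 12 gene lists, 1 point per gene, filled red where the adjusted p was below 0.05 and open where it was not, with the list median as a vertical bar. The 3 PHO genes lie at 1.32 to 2.89, and the median of hexose transporters lies at -0.67.

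Genes of RNA 3′ end formation and RNA decay changed in part. Of 19 cleavage, polyadenylation and termination factors 8 rose and 1 fell; the phosphatase gene ssu72 rose (0.93, SE 0.11), as did cft2 (0.53) and rhn1 (0.49), and dis2 fell (-0.38; list adjusted p = 0.23). The median of that list was 0.05, and -0.01 with cyclic loess, which also ended the call of rhn1 (adjusted p = 0.076) and left 5 members higher and 2 lower. GC-corrected offsets gave 10 higher and 4 lower. The entry clp1 of that list names a Cdc14-like phosphatase in this species and not a cleavage factor. In the nuclear RNA elimination list 6 of 9 members rose, including rrp6 (0.62, SE 0.10) and mtl1 (0.47), and mmi1 fell (-0.18; list adjusted p = 0.14). In that list 6 rose and 0 fell with total counts, 4 rose and 1 fell with cyclic loess, and 6 rose and 2 fell with GC-corrected offsets. Of 9 meiotic targets of Mmi1, 3 rose: num1 (mcp5), rec10 (0.53) and mug9 (1.77). The call of mug9 was lost with DESeq2 (adjusted p = 0.082) and without wild-type replicate 1 (1.37, 0.084) or 3 (1.35, 0.088) or deletion replicate 1 (1.71, 0.074) or 2 (1.78, 0.062). Without wild-type replicate 2 mug9 measured 3.37. The list adjusted p was 0.14, and 0.034 with cyclic loess, where 5 members rose. Among 108 tested mug and meu genes 19 were higher and 22 lower, with mug106 at -1.16 (list adjusted p = 0.27). The balance turned with the scaling, to 22 higher and 17 lower with total counts, 15 and 29 with GC-corrected offsets, and 11 and 34 with cyclic loess. In the phosphate signalling list asp1, the kinase and pyrophosphatase of inositol pyrophosphates, rose (0.70, SE 0.06), and vtc4, of polyphosphate synthesis, rose (0.28). The gene pqr1, of a ubiquitin ligase with an SPX domain, fell by 0.12. Leaving out any library but wild-type replicate 3 ended that call, with values from -0.12 to -0.08 and adjusted p up to 0.21, as did total counts and cyclic loess. The 8 members of the list had a median of -0.01, a mean of 0.06 and an upward test (adjusted p = 0.79), and the median turned positive with total counts, the upper quartile, cyclic loess and without the mitochondrial and rRNA genes.

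Of 10 flocculin genes and regulators 4 rose, pfl3, pfl8 (0.95), pfl9 (0.69) and the regulator mbx2 (0.96; list adjusted p = 0.090, but 0.031 without deletion replicate 3 and 0.041 with GC-corrected offsets). With total counts and with GC-corrected offsets 6 of them rose, and with cyclic loess 5 rose and 2 fell. Copper and zinc transport genes went both ways, with ctr4 (0.52) and zrt1 (0.70) higher and zhf1 (-0.52) and ctr5 (-0.29) lower (median -0.10, mean 0.06, downward test with adjusted p = 0.60). The call of zrt1 was lost with DESeq2 (adjusted p = 0.068) and without wild-type replicate 2 (0.54, 0.081) or deletion replicate 3 (0.68, 0.0502), and without wild-type replicate 3 it measured 1.06. All 4 tested auxotrophic marker genes fell, including leu1 (-0.39, SE 0.05) and ade6 (-0.25; adjusted p = 0.030, and adjusted p = 0.34 with an estimated correlation; 0.069 with GC-corrected offsets, 0.087 with cyclic loess). Of 7 M mating type markers none passed in edgeR or DESeq2, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.40, but 0.022 without deletion replicate 1). Of 3 P markers map2 (-0.72) and map4 (-0.24) were lower (list adjusted p = 0.10), and map4 lost its call without wild-type replicate 2 (-0.23, adjusted p = 0.066) or deletion replicate 3 (-0.14, adjusted p = 0.056). With total counts map4 also lost its call (-0.17, adjusted p = 0.053), which left 1 P marker lower. With cyclic loess 3 were lower. Among 6 sexual differentiation genes ste4 rose (0.56) and mei2 fell (-0.93; list adjusted p = 0.71). Of 5 tested Tf2 and tlh elements 3 fell, tlh2 (-2.82), Tf2-11 (-0.97) and Tf2-6 (-0.94), which share 90.9% to 100% of their 50-mers with other copies and are uncertain (list adjusted p = 0.10). The call of Tf2-6 was lost with DESeq2 (adjusted p = 0.15) and without wild-type replicate 1 (-0.84) or 3 (-0.84) or deletion replicate 2 (-0.83) or 3 (-0.75). It was also lost with total counts (-0.88, adjusted p = 0.056), with no filter (-0.93, 0.064) and with cyclic loess (-0.44, 0.28). With total counts and with cyclic loess 2 of the 5 elements were lower. The Duf89 list held duf89 alone.

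Annotated non-coding RNAs were lower as a class (median -0.22, camera adjusted p = 2.4e-04, and adjusted p = 0.34 with an estimated correlation). Those with the smallest adjusted p were omt3, pof9-antisense-1, cwf19-antisense-1 (-1.16, SE 0.06) and SPNCRNA.1063 (-1.10). Of 596 antisense RNAs 191 fell and 54 rose, and of 347 intergenic RNAs 73 fell and 29 rose. Whether the counting used strand is not given in the sources used here, so antisense values are uncertain. Adjusted over the list alone, the counts equalled those over all genes except in 5 lists. These were histones (10 lower), cytosolic ribosomal proteins (93 lower), RNA elimination (2 lower), mug and meu genes (17 higher, 21 lower) and non-coding RNAs (70 higher, 241 lower). Of 27 lists 8 passed camera with its preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05, and 23 passed fry. With an estimated correlation even the mitochondrial list did not pass (adjusted p = 0.34), though all 7 tested members were lower with a median of -10.1. Failing in that setting therefore does not argue against a shift of a list. Fry asks whether members shift, not whether they shift more than other genes. Other splits of the same libraries gave up to 10 lists. Each of those splits mixes the groups and can keep part of a group difference. Their list counts therefore cannot tell whether the reported lists exceed chance, and the splits give the list tests no backing. Over all 6045 tested genes 1739 were higher and 1486 lower, and counts of list members are to be read against that background.

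The deposited comparison was close to the refit. The authors' deposited table holds 1652 genes higher and 1632 lower at an adjusted p below 0.05, with 30 and 177 of them at least 2-fold. Across 6045 genes its log2 fold changes correlated with the refit at a Pearson r of 0.9997. Of the calls among the 6042 genes with an adjusted p in both, 3091 were shared, all in the same direction, 132 were made only in the refit and 172 only in the deposited table.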

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

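The fits without mitochondrial and rRNA genes, with GC-corrected offsets, with cyclic loess, on genes with little repeated sequence and with protein genes only in 2 lists were chosen after the data were seen; the others were planned. The directions and calls of duf89, pho1, pho84 and tgp1 held under every alternative run, with ranges of -2.03 to -1.57, 1.68 to 1.94, 1.26 to 1.51 and 2.75 to 3.01. An adjusted p below 0.01 left 1152 genes higher and 932 lower. At 2-fold or more, the stricter filter left 18 genes higher and 37 lower, and protein-coding genes alone left 44 lower, by construction of fewer genes tested. Leaving out 1 library gave 31 to 52 genes higher by at least 2-fold, the most without wild-type replicate 3; the cause was not tested. The other counts over all genes stayed within 1.5 times of those reported; counts of list members did not in all lists. Cyclic loess gave 1323 higher and 1458 lower and shared 2155 calls with the reported fit, all in the same direction. With an estimated correlation 0 lists passed and with fry 23. The mitochondrial list, with all 7 tested members lower, was among those that did not pass with an estimated correlation. That setting therefore cannot decide whether a list shifted. As fry does not compare members with other genes, its count answers another question. Why the camera settings differed was not tested. Among the named genes 1 call turned: the log2 fold change of pqr1, -0.12 as reported, was 0.00450 with cyclic loess (adjusted p = 0.94). Its adjusted p ran from 0.0049 to 0.94 over its alternatives, and the cause was not tested. Replicate numbers did not pair the libraries (same-number correlations of -0.13, -0.17 and 0.26). The replicate block gave 1900 genes higher and 1633 lower and 8 lists. With 10 splits of 6 libraries no share can fall below 0.1. The real split gave 1739 higher, 1486 lower, 34 and 150 by at least 2-fold (1 of 10 splits each), and the highest other split 0 by edgeR and DESeq2, with at most 100 genes at an unadjusted p under 0.05. It gave 8 lists, 3 of 10 splits gave as many, and the highest other gave 10. Every other split mixes the groups, so a group difference widens its spread, and its 0 calls do not test the gene counts. In simulated data of this depth, in which 200 genes were changed, the test found 54% of the smallest changes made. In the real data 53.3% of the genes tested passed, and the Benjamini-Hochberg cutoff depends on that share. The simulated share therefore does not carry over, and how many small changes were missed was not tested.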

Other observations

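The tests in this part and what would count for or against each explanation were chosen after the results were seen, except the criterion for the GC correction of ribosomal protein genes. Genes of amino acid biosynthesis, a list written after their values were seen, had 32 of 44 members lower and 3 higher (median -0.28, and -0.19 with cyclic loess). As the list was chosen for the pattern, no test of it is given. The members that fell most were arg12 (-0.98), arg5 (-0.87), gdh1 (-0.81), arg4 (-0.81) and ser3 (-0.81), whereas tyr1 (0.55) and his6 (0.49) rose. Nuclear-coded respiratory chain and ATP synthase genes did not pass camera (11 of 43 higher, 10 lower, adjusted p = 0.79 over 7 added lists), nor did proteasome genes (6 of 33 higher, 13 lower, adjusted p = 0.48). Mitochondrial ribosomal protein genes had 15 of 38 higher and 7 lower (adjusted p = 0.48), and protein-coding genes within 100 kb of the ends of chromosomes I and II had 16 of 70 higher and 19 lower (adjusted p = 0.92). The medians of these 4 lists changed sign with cyclic loess.

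The mitochondrial transcripts at 0 in the deletion are the first pattern to weigh. All 22 mitochondrial features with a wild-type count were at 0 in the 3 deletion libraries, and 0 nuclear genes with a wild-type mean of at least 10 counts were. A candidate explanation is that mitochondrial features were not counted in the deletion libraries, which would leave exactly such zeros. Less carry-over of RNA without poly(A) tails is argued against as the whole cause only if it lowered mitochondrial and nuclear rRNA counts alike. A fall like that of the raw nuclear rRNA counts would then have left 642 mitochondrial counts. Whether nuclear rRNA measures carry-over in these libraries was not tested. Nuclear snRNA, snoRNA and tRNA genes had a median of 0.09, with 1 of 30 tested higher and 4 lower. A loss of mitochondrial RNA in the mutant was not tested and stays open, as no read or alignment was used here.

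Antisense RNAs were lower in the deletion more often where the opposite gene was strongly expressed. Across 581 antisense RNAs with an overlapping protein-coding gene, Spearman's rho of the log2 fold change with the expression of that gene was -0.34 (permutation p = 1e-05, the smallest that 100000 resamples can give). Among the 194 with the most expressed partners 75 fell and 5 rose (median -0.43), which is consistent with a larger share of sense reads on the antisense strand in wild type. Among the 194 with the least expressed partners 45 fell and 32 rose (median -0.14, two-sided exact binomial p = 0.17), which leaves open whether that explanation covers these. Intergenic RNAs also fell more often than they rose, with 73 of 347 lower and 29 higher. The annotation places these between genes, so that explanation does not readily cover them. An effect of the deletion on antisense RNA stays open and untested.

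Cytosolic ribosomal protein mRNAs were lower by a median of -0.18 over 131 protein genes. With GC-corrected offsets the median was -0.084, which met the criterion for GC content fixed before that value was seen, so GC content may account for much of the shift. The list still passed camera with its preset correlation (adjusted p = 0.015), but without the GC correction it did not pass with an estimated correlation (adjusted p = 0.60), and whether GC content is the whole cause stays open. The median lay at percentile 12.4 of lists of other genes matched on mean count, whose median was -0.16, and cyclic loess brought it to -0.01. The loess fit includes the ribosomal protein genes, so the value of -0.01 is partly built in. A trend with transcript abundance, in which abundant mRNAs tended to be lower, may therefore account for the fall. A biological effect of the deletion on abundant mRNAs was not tested apart from such a trend. Not every list followed it. The 33 protein genes of ribosome biogenesis had a median of 0.23, against -0.05 in lists matched on mean count (percentile 100). The respiratory chain, mitochondrial ribosome, proteasome and subtelomeric lists lay between percentiles 20.5 and 95.9. The amino acid list, chosen for its pattern, is left out.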
